A study of Mus musculus with 16 samples.

How the data were processed

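Polyadenylated RNA from mouse embryos was measured in 16 libraries, 2 in each of 8 groups. According to the labels, gut tubes of embryos at the 13-somite stage (E8.75) were dissected free of other tissue after a brief enzyme treatment. They were taken whole as bulk tissue, as cells dissociated at warm temperature with enzymes, or as 4 sections from anterior to posterior. Embryonic (emVE) and extraembryonic (exVE) visceral endoderm came from E7.5. The files deposited by the authors hold raw counts per gene symbol, with no normalization: whole numbers with a different total in each sample. The submitters' processing notes name STAR as the aligner; its version, the genome build, the annotation and the counting program are not given in the sources used here, and neither is the number of embryos behind a library.

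Each file had 26795 entries. The 32 symbols listed more than once were summed, which gave 26761 symbols, of which 25562 matched a table of mouse gene names and were printed in its spelling. Totals ran from 57061536 to 84509973 counts per library. A gene at 0 counts in both libraries of a group was set against a floor of 3 counts over the group, and such fold changes are given as "at least"; floors and levels cover counting error only. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 17313 genes with at least 99.993% of each library's counts.

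Groups were compared with edgeR 4.0.16 in R 4.3.3. All 16 libraries entered 1 quasi-likelihood fit with a coefficient per group and TMM normalization, which gave 8 residual degrees of freedom (prior degrees of freedom 3.74, common dispersion 0.0592). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided; every adjusted p of a gene comes from this fit unless DESeq2 is named. There were 7 comparisons of 2 groups and 1 F-test for any difference among the 4 sections. For 33 gene lists on gut regions, other lineages and cell types, signalling, stress and metabolism, members that rose or fell were counted over all genes tested and adjusted over the list alone. Some genes, such as Fgf8, Sox2, Hnf4a and Hoxa13, stand on more than 1 list, so results of such lists are not independent. Each list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with the other genes, while fry tests whether the list's genes move 1 way on balance. Fry values are printed only for dissociated against bulk tissue.

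Libraries of a group differed far beyond sampling noise, with a chi-square per gene between 34.3 and 395, so they were never merged. Both libraries of a group carry numbers that recur across groups, but the labels do not say what a shared number means. Deviations from group means had correlations across genes from -0.108 to 0.216 between libraries of the same number over the comparisons. The highest was for the posterior against the anterior section. With 2 libraries per group each comparison gives a single such value, which cannot show whether the numbers mark pairs. The numbers were not used as pairs, since the labels do not explain them, and a replicate block was tried as an alternative. The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, from genes past the threshold whose libraries do not overlap between the groups, the 8 largest log2 changes in each direction (5 between neighbouring sections) with a mean log2 CPM of at least 3 in the higher group. Unnamed predicted genes are left out. It adds up to 4 members of each list with the smallest adjusted p, all Hox genes, and 9 key genes. Xist and Y-linked genes, the members set out by library and the genes of the observations were chosen after the values were seen.

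The alternatives were RLE size factors, no filter except for genes at 0 in every library, the replicate block, only the compared groups in the fit, each library left out in turn, and DESeq2 1.42.0 (Wald test, or a likelihood ratio test for the sections). A fit with the mean level of 4 Y-linked genes as a covariate was added after the data were seen. A group left with 1 library is assumed to vary like the other groups. Alternatives planned for normalized values did not apply, since the files hold counts. The symbols were not joined to genome positions, and no splicing, isoform or single-cell analysis was done; single-cell data of the study were not analysed here.

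The steps were tested on simulated data with 200 changed genes per comparison. At folds of 1.5, 2 and 4, the share recovered was 2.99%, 46.3% and 90.9% for exVE against emVE and 4.48%, 43.3% and 92.4% for the posterior against the anterior section. It was 14.9%, 41.8% and 97.0% for the anterior-midgut against the anterior section, and 7.46%, 44.8% and 90.9% for the midgut-posterior against the anterior-midgut section. For the posterior against the midgut-posterior section it was 5.97%, 50.7% and 83.3%, for dissociated cells against bulk tissue 8.96%, 41.8% and 87.9%, and for bulk gut tubes against emVE 7.46%, 52.2% and 83.3%. Between 2 and 7 calls per simulation were false. The simulations gave a gene the same dispersion in every group. The real dissociated libraries differed far more, with a chi-square per gene of 395 against 118 for the posterior section, the next highest. The shares recovered for dissociated cells against bulk tissue may therefore be too high for the real data.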

Results

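The 16 libraries covered 8 groups of mouse embryonic tissue with 2 libraries each. Visceral endoderm at E7.5 came as an embryonic (emVE) and an extraembryonic (exVE) part. Gut tubes at E8.75 came as undissociated bulk tissue, as dissociated cells, and as 4 sections along the body axis (anterior, anterior-midgut, midgut-posterior and posterior). Levels are given as CPM, counts scaled to the library total multiplied by its TMM factor. They are printed as mean ± SD with n = 2 per group. The TMM factors were 0.787 and 0.775 in the exVE libraries and 1.02 and 1.01 in the emVE libraries. Levels in exVE are thus higher, relative to emVE, than they would be on library totals alone. Adjusted p-values measure the spread between these samples alone, since the labels do not say whether 2 libraries came from separate embryos or pools.

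At E7.5, the embryonic part of the visceral endoderm carried many axial, mesodermal and signalling transcripts that were far lower in the extraembryonic part. All 8 measured notochord genes fell in exVE relative to emVE (8 adjusted over the list alone), with a median log2 fold change of -6.01 (adjusted p = 1.32e-09 by camera, and adjusted p = 0.233 with an estimated correlation). T (Brachyury), a transcription factor of nascent mesoderm and notochord, stood at 6.89 ± 2.46 CPM in exVE and 386 ± 9.10 CPM in emVE. Foxj1, a regulator of motile cilia, stood at 7.87 ± 2.16 and 202 ± 1.63 CPM, and the ligand Shh at 0.0605 ± 0.0856 and 21.4 ± 3.85 CPM. Of 16 epiblast and nascent mesoderm genes, 13 fell (13 adjusted over the list alone), among them Fgf5 and the Nodal antagonist Lefty2 (list adjusted p = 7.22e-05, and 0.233 as the adjusted p with an estimated correlation). Hedgehog signalling genes followed, with 7 of 10 lower in exVE, including the target Gli1 (0.278 ± 0.0631 against 23.5 ± 6.80 CPM), and 1 higher (7 and 1 adjusted over the list alone). That list had an adjusted p = 6.28e-06, and an adjusted p = 0.233 with an estimated correlation.

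Endoderm genes of the embryonic region were also lower in exVE. Of 12 anterior visceral endoderm genes, 9 fell (10 adjusted over the list alone), including the secreted antagonists Cer1, Sfrp1 and Dkk1. Cer1 stood at 6.10 ± 7.14 CPM in exVE and 284 ± 46.2 CPM in emVE, a log2 change of -5.54 (SE 0.83, adjusted p = 0.00085). Camera gave that list an adjusted p = 0.00669, and an adjusted p = 0.298 with an estimated correlation. Among 13 definitive endoderm genes, 10 fell and 1 rose, also adjusted over the list alone, with Foxa1 at 7.53 ± 1.47 against 107 ± 6.07 CPM and the chemokine receptor Cxcr4 at 1.07 ± 0.195 against 32.1 ± 6.60 CPM. Its adjusted p was 7.46e-05, and the adjusted p was 0.307 with an estimated correlation. Aldh1a2, which makes retinoic acid, stood at 0.220 ± 0.202 CPM in exVE and 66.6 ± 16.7 CPM in emVE. Hoxb1, the Hox gene with the smallest adjusted p here (5.33e-07), stood at 0.297 ± 0.0205 and 41.7 ± 5.49 CPM. Of 12 Hox genes of groups 1 to 4, 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0372, adjusted p = 0.62 with an estimated correlation, 0.0863 without exVE replicate 2, 0.0509 without emVE replicate 2 and 0.143 with no filter on low counts). Of 11 in groups 5 to 8, 3 rose and 1 fell (3 and 0 adjusted over the list alone; median 1.76, adjusted p = 0.124), and Hoxb7 rose by a log2 change of 2.87 (SE 0.46, adjusted p = 0.000485). Several genes had 0 counts in both exVE libraries, so that the neuropeptide gene Gal was at least 496-fold lower, the somite gene Meox1 at least 331-fold lower and Wnt8a at least 312-fold lower, against a floor of 3 counts over the group.

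The extraembryonic part was higher in lysosome genes. Of 16 lysosome genes, 13 rose in exVE (14 adjusted over the list alone), with a median log2 change of 1.16 (adjusted p = 1.64e-05, and adjusted p = 0.359 with an estimated correlation). Lamp1, a lysosomal membrane protein, stood at 1525 ± 95.4 against 693 ± 58.2 CPM. Lrp2, the endocytic receptor megalin, rose from 384 ± 31.0 to 1962 ± 107 CPM, a log2 change of 2.36 (SE 0.25, adjusted p = 3.64e-05). It was 1 of 4 visceral endoderm genes of 23 that rose (3 adjusted over the list alone), while the list's median log2 change was 1.48 (adjusted p = 0.00789, and adjusted p = 0.686 with an estimated correlation). The secreted carrier genes Afp (912 ± 100.4 against 759 ± 130 CPM, adjusted p = 0.84) and Ttr (1743 ± 40.4 against 900 ± 123 CPM, adjusted p = 0.411) did not pass. The fit of all 16 libraries takes in the spread of gut tube libraries, which limits these calls and the count of 4. In a fit of the exVE and emVE libraries alone, the log2 change was 0.87 for Ttr (SE 0.11) and 0.18 for Afp (SE 0.13). The list's median SE was 0.1056 in that fit and 0.7445 in the fit of all 16. Outside the lists, the fatty acid binding protein gene Fabp1 rose from 4.87 ± 1.98 to 51.8 ± 3.96 CPM and the dipeptidase gene Dpep1 from 1.56 ± 0.268 to 16.4 ± 1.16 CPM.

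Markers of other cell types moved with this comparison on both sides. Of 11 primitive blood genes, 7 rose in exVE, among them the embryonic globin Hbb-bh1 (19.0 ± 2.16 against 4.04 ± 1.52 CPM), and of 12 endothelial genes 5 rose, among them Pecam1 (9.06 ± 3.07 against 1.87 ± 0.562 CPM); 7 and 5 did so adjusted over the list alone. The blood list had an adjusted p = 0.00468, an adjusted p = 0.344 with an estimated correlation and 0.0935 with only these groups in the fit. The endothelial list had an adjusted p = 0.0301, an adjusted p = 0.672 with an estimated correlation, 0.202 without exVE replicate 1, 0.085 without emVE replicate 1 and 0.185 with only these groups in the fit. In the other direction, 7 of 11 paraxial mesoderm genes and 8 of 16 cardiac and splanchnic genes fell in exVE (7 and 8 adjusted over the list alone; adjusted p = 0.000411 and 0.0108, and adjusted p = 0.307 and 0.504 with an estimated correlation). Mitochondrial transcripts took 6.65% and 5.75% of the counts in the exVE libraries and 5.48% and 4.77% in the emVE libraries. In all, 7605 of 17313 genes passed in edgeR, 3476 higher and 4129 lower in exVE, and 4462 of them by more than 1 on the log2 scale.

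**Figure D1:**
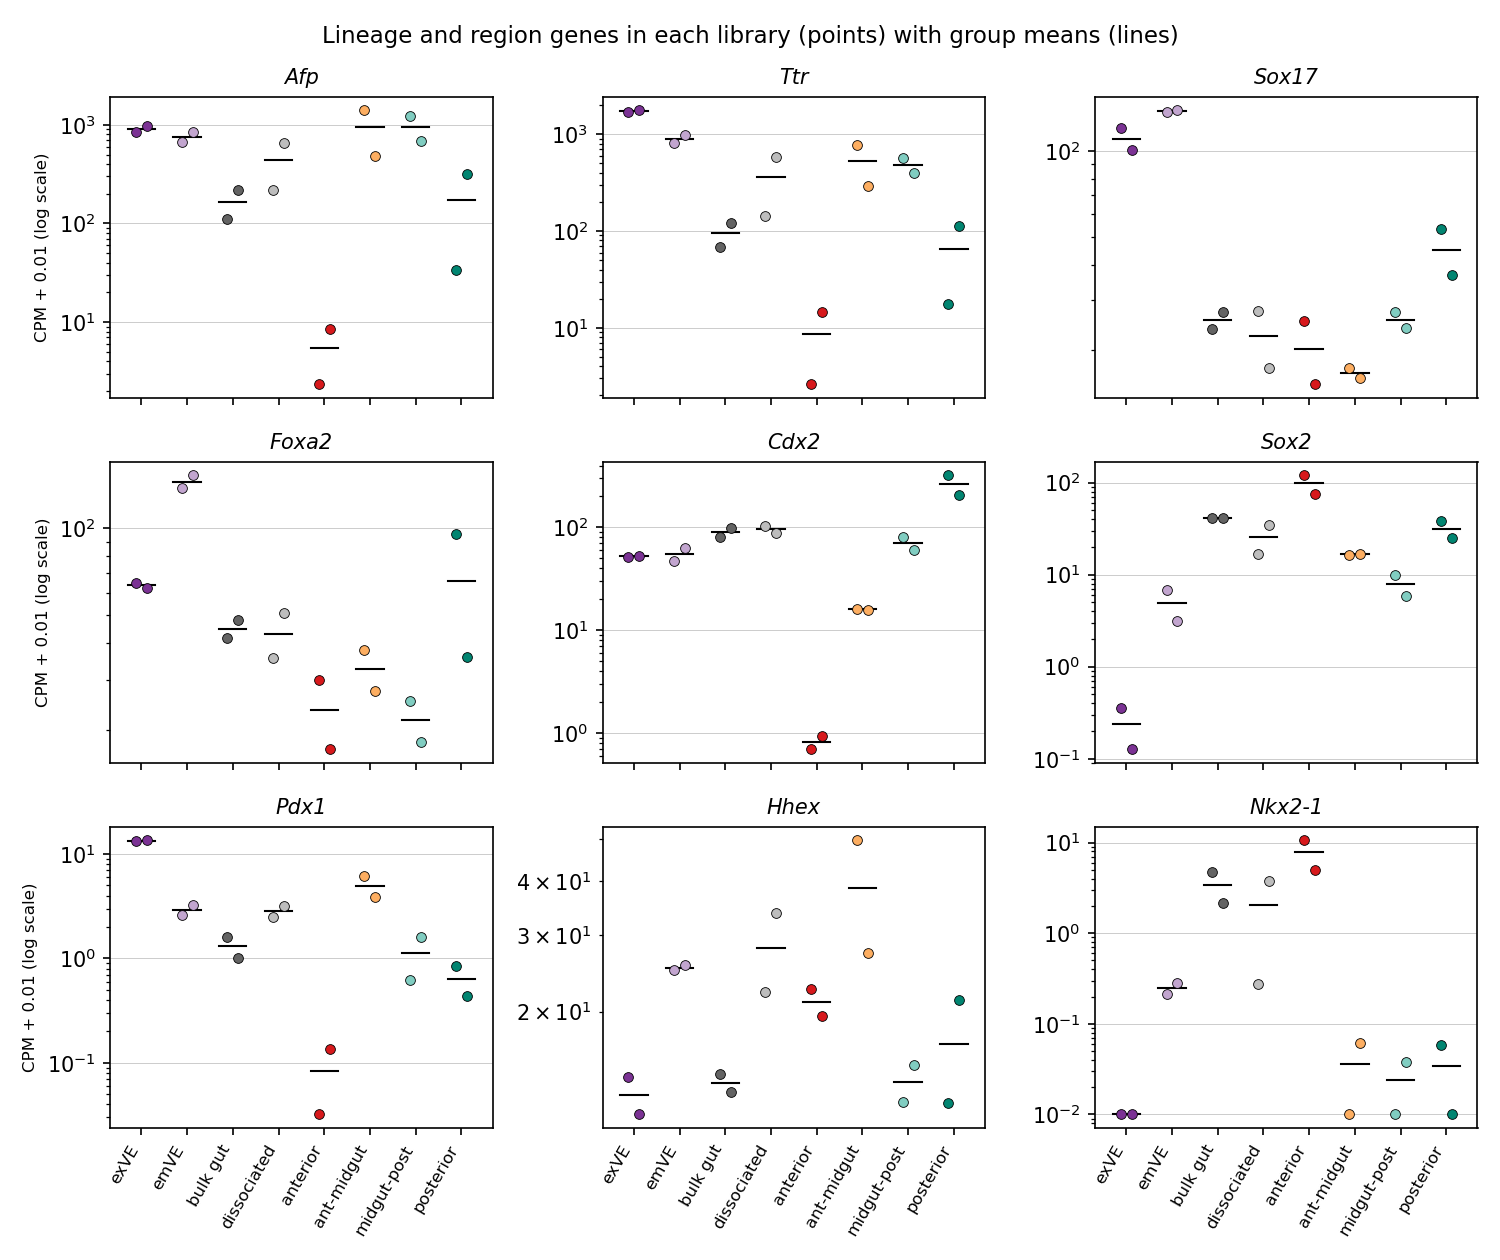
CPM plus 0.01 on a log axis for 9 lineage and region genes in the 8 groups; each point is a library and each line a group mean (n = 2). Cdx2 reached 265 CPM in the posterior section against 0.809 CPM in the anterior one, and Afp reached 947 and 955 CPM in the middle sections, beside 912 CPM in exVE.

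**Figure D2:**
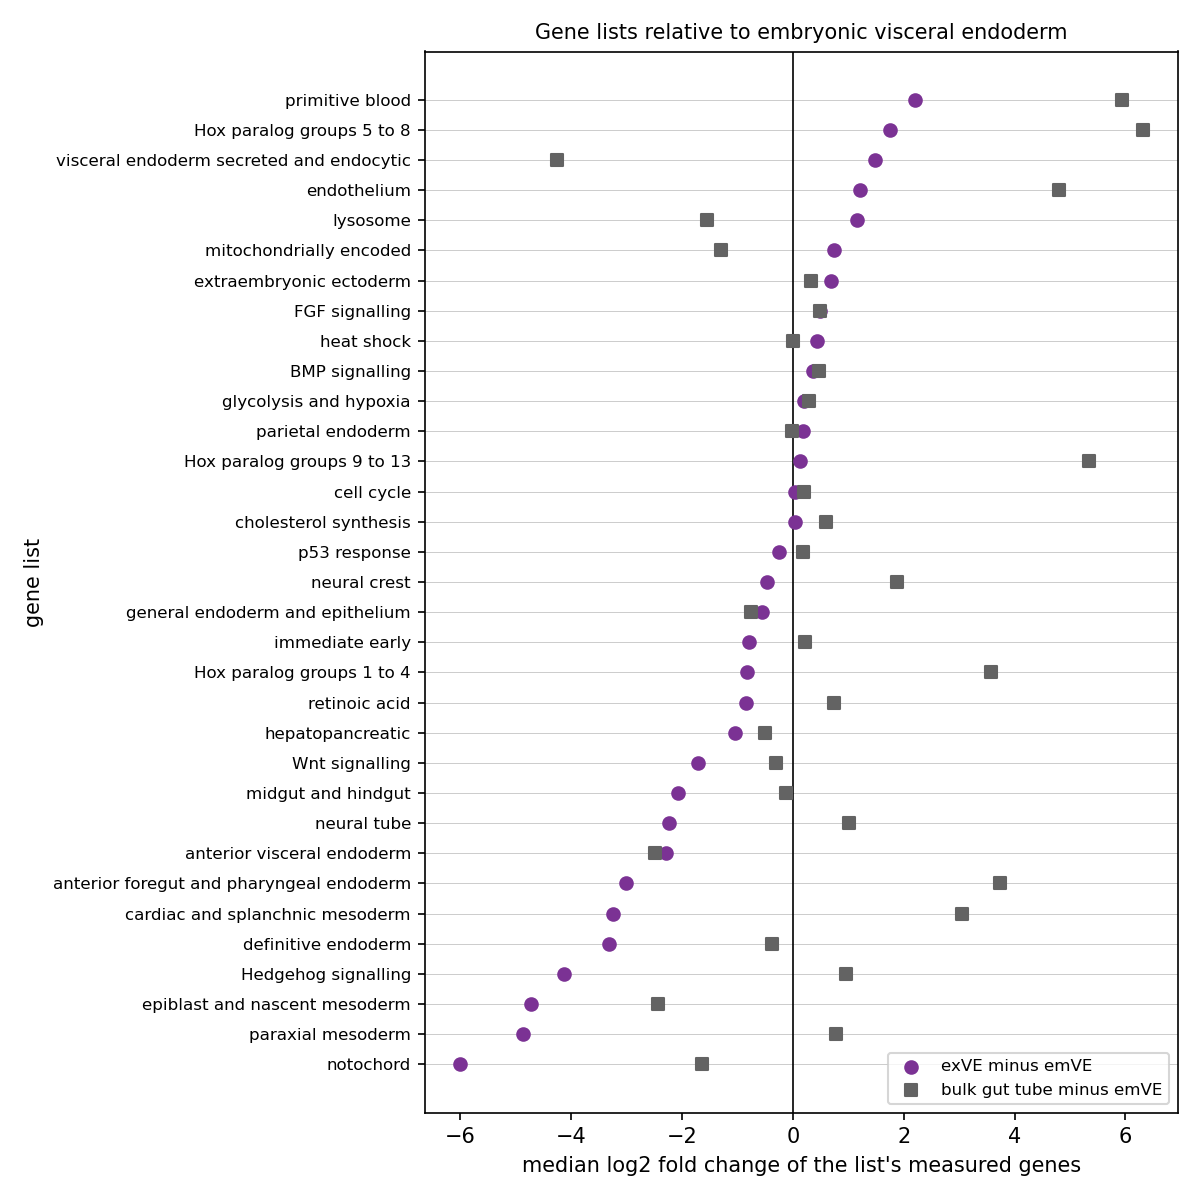
Median log2 fold change of the measured genes of 33 lists, relative to emVE, with genes at 0 counts in 1 group set to their bound; circles show exVE and squares show bulk gut tubes. The visceral endoderm list lay at 1.48 in exVE and -4.26 in bulk gut tubes, and the notochord list at -6.01 in exVE.

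Along the gut tube at E8.75, foregut genes peaked at the anterior end, visceral endoderm and hepatopancreatic genes in the middle, and Hox genes of groups 9 to 13 and hindgut genes at the posterior end. In a test for any difference among the 4 sections, all 17 measured anterior foregut and pharyngeal genes passed and each had its highest mean in the anterior section. Of 23 visceral endoderm genes, 20 passed, 14 of them with their peak in the anterior-midgut section and 5 in the midgut-posterior section. No list member passed between these 2 sections. The list medians were 7.55 and 5.87 log2 CPM in anterior-midgut replicates 1 and 2, against 6.87 and 6.55 in the midgut-posterior libraries. The split of peaks thus leans on anterior-midgut replicate 1. Afp stood at 5.45 ± 4.41, 947 ± 654, 955 ± 374 and 174 ± 198 CPM from the anterior to the posterior section (adjusted p = 0.00476). Of 12 hepatopancreatic genes, 8 passed, 6 with a peak in the anterior-midgut section, where Pdx1, a regulator of pancreas formation, reached 4.98 ± 1.61 CPM. Of 16 cardiac and splanchnic genes, 12 passed and 9 peaked in the same anterior-midgut section. Each library pools all cells of a section. The levels of heart, neural, vessel, blood and mesoderm genes therefore do not tell whether gut tube cells or other cells in the sample carried them. Wnt genes peaked posteriorly in 12 of 14 that passed, while FGF genes that passed had their peak in the anterior section in 7 cases and in the posterior section in 4. Overall 2236 genes passed, with peaks in the anterior (635), anterior-midgut (577), midgut-posterior (388) and posterior (636) sections; 1244 passed without anterior replicate 1. None of the 12 endothelial, 11 blood, 13 heat shock and 16 cell cycle genes passed in this edgeR test, which called 4314 of all genes at an unadjusted p under 0.05, and DESeq2 called 3739 of all genes after adjustment.

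**Figure D3:**
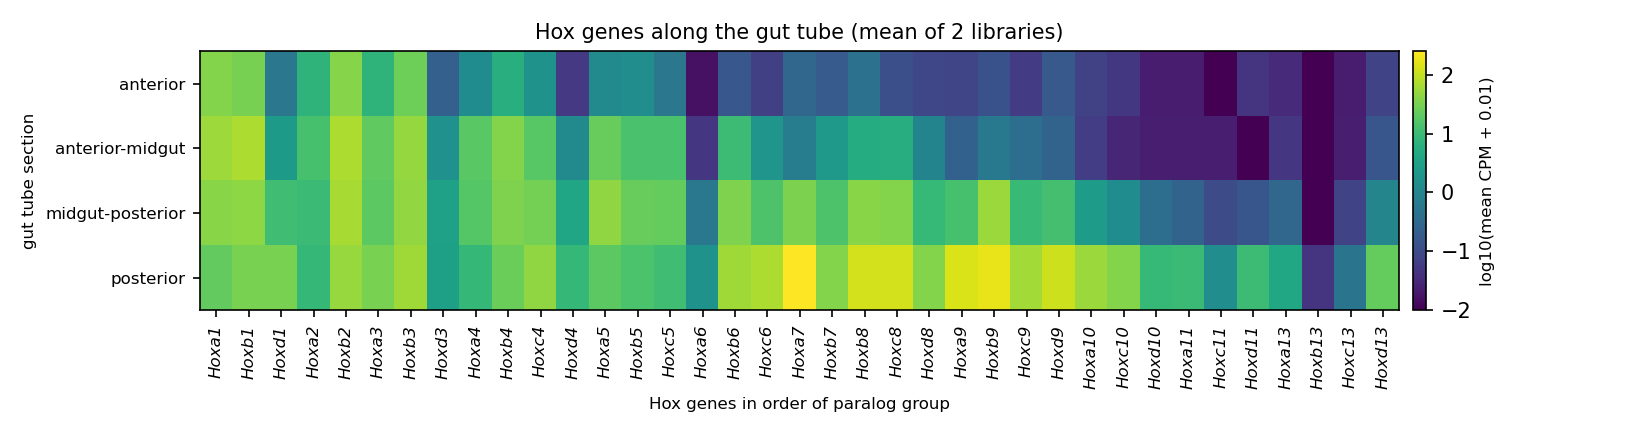
Heat map of mean CPM (log10 after adding 0.01, n = 2) of 37 Hox genes in order of paralog group, with 1 line for each gut tube section from anterior to posterior. All 14 measured genes of paralog groups 9 to 13 had their highest mean in the posterior section, against 8 of 11 in groups 5 to 8 and 5 of 12 in groups 1 to 4.

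The ends of the tube differed in regional transcription factors. All 11 Hox genes of paralog groups 5 to 8 rose in the posterior relative to the anterior section (11 adjusted over the list alone; adjusted p = 1.59e-49 by camera). They did so with a median log2 change of 8.21, and Hoxc8 reached 123 ± 3.19 against 0.107 ± 0.0267 CPM. Of 14 genes in paralog groups 9 to 13, 12 rose (13 adjusted over the list alone), with a median of 9.52, or 9.43 with genes at 0 counts set to their bound (adjusted p = 2.24e-33). Of 12 midgut and hindgut genes, 8 rose (9 adjusted over the list alone; adjusted p = 4.46e-28). Cdx2, which specifies the intestine, stood at 265 ± 79.9 against 0.809 ± 0.175 CPM, a log2 change of 8.36 (SE 0.25, adjusted p = 1.25e-07), and Cdx4 at 187 ± 40.8 against 0.257 ± 0.207 CPM. These lists also passed with an estimated correlation, with adjusted p-values of 0.00174 for the groups 5 to 8, 0.00216 for the groups 9 to 13 and 0.00174 for midgut and hindgut genes. In the other direction, 14 of 17 foregut genes fell (17 adjusted over the list alone), with a median of -4.22 (adjusted p = 2.77e-22, and adjusted p = 0.0527 with an estimated correlation). Pax1, a pharyngeal pouch gene, stood at 0.0183 ± 0.0259 CPM in the posterior and 77.0 ± 42.3 CPM in the anterior section. Nkx2-5 fell as well, with a log2 change of -9.25.

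Several heart and neural genes fell in the posterior section. Of 16 cardiac and splanchnic genes, 7 fell and 1 rose (10 and 3 adjusted over the list alone), with Myl7 at 2.76 ± 1.76 against 106 ± 43.1 CPM. That list had an adjusted p = 0.00032, an adjusted p = 0.298 with an estimated correlation and 0.145 without posterior replicate 1. Of 8 neural crest genes, 3 fell (6 adjusted over the list alone; adjusted p = 0.000554, and adjusted p = 0.212 with an estimated correlation). Of 12 neural tube genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with an adjusted p = 0.03, an adjusted p = 0.238 with an estimated correlation, 0.143 without anterior replicate 2 and 0.158 without posterior replicate 1.

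Signalling genes differed between the ends too. Of 16 Wnt genes, 10 rose in the posterior section and 1 fell (11 and 2 adjusted over the list alone), with Wnt5b at 135 ± 70.1 against 12.2 ± 1.95 CPM and Rspo3 at 96.2 ± 40.9 against 1.55 ± 0.944 CPM. That list had an adjusted p = 4.77e-11, and an adjusted p = 0.078 with an estimated correlation. Ihh, a Hedgehog ligand, stood at 51.4 ± 24.2 CPM in the posterior and 1.18 ± 0.351 CPM in the anterior section. Of 11 retinoic acid genes, 4 fell, among them the receptor gene Rarb and the degrading enzyme gene Cyp26c1, and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00047, and adjusted p = 0.0516 with an estimated correlation). Of 12 p53 response genes, 4 rose (6 adjusted over the list alone), with an adjusted p = 1.22e-05 and an adjusted p = 0.0283 with an estimated correlation. The cell cycle inhibitor gene Cdkn1a stood at 59.3 ± 33.0 against 5.65 ± 0.285 CPM. Of 16 epiblast and nascent mesoderm genes, 6 rose and 2 fell (7 and 4 adjusted over the list alone), with T at 339 ± 162 against 42.1 ± 18.1 CPM (list adjusted p = 0.00133, and adjusted p = 0.238 with an estimated correlation). Msgn1, a presomitic mesoderm gene, was at least 526-fold higher.

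In total 1370 genes passed between the posterior and anterior sections, 697 higher and 673 lower in the posterior one. The count was 615 without anterior replicate 1, 707 without anterior replicate 2 and 685 without posterior replicate 1, and 2280 with DESeq2. Of 104 named genes past the threshold, 61 stayed past it with each library left out in turn; each gene given above for this comparison was among them. No sex-linked gene examined passed between these sections. Xist, which silences an X chromosome in female cells, stood at 400.0 ± 45.5 CPM in the anterior and 89.98 ± 19.4 CPM in the posterior section (adjusted p = 0.54), and the Y-linked gene Uty at 9.77 ± 0.945 and 21.5 ± 2.47 CPM (adjusted p = 0.457).

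The step from the anterior to the anterior-midgut section brought up visceral endoderm genes and lowered FGF genes. Of 23 visceral endoderm genes, 19 rose (20 adjusted over the list alone), with a median log2 change of 6.21 (adjusted p = 1.07e-28, and adjusted p = 0.108 with an estimated correlation). The retinol carrier Rbp4 rose from 8.46 ± 3.53 to 640 ± 437 CPM, a log2 change of 6.24 (SE 0.70, adjusted p = 0.00227), and Mttp, which loads lipoproteins, from 14.0 ± 0.0822 to 142 ± 74.4 CPM. Of 13 FGF genes, 11 fell (12 adjusted over the list alone; adjusted p = 1.07e-28, and 0.0076 as the adjusted p with an estimated correlation). Etv5, an FGF target, went from 122 ± 20.2 to 32.8 ± 1.98 CPM, and the feedback inhibitor Spry4 from 11.2 ± 0.922 to 2.65 ± 0.696 CPM. Of 12 hepatopancreatic genes, 4 rose (7 higher and 1 lower adjusted over the list alone), including Pdx1 and Hnf4a, and the list passed with an estimated correlation as well (adjusted p = 0.0226). Of 11 Hox genes in groups 5 to 8, 9 rose, and of 12 in groups 1 to 4, 6 rose (9 and 11 adjusted over the list alone; adjusted p = 0.0158 and 0.0414 with an estimated correlation). Foregut genes fell in 11 of 17 cases (15 adjusted over the list alone), with an adjusted p = 6.78e-19 and an adjusted p = 0.0827 with an estimated correlation.

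Of 16 lysosome genes, 6 rose in the same step (13 adjusted over the list alone), with an adjusted p = 4.83e-11 and an adjusted p = 0.149 with an estimated correlation. Neural tube genes fell in 4 of 12 cases (7 adjusted over the list alone), with a median log2 change of -2.65, or -2.21 with genes at 0 counts set to their bound (adjusted p = 3.74e-06, and 0.0414 as the adjusted p with an estimated correlation). Of 8 neural crest genes, 2 fell (4 adjusted over the list alone), with an adjusted p = 0.0019, an adjusted p = 0.226 with an estimated correlation and 0.206 without anterior replicate 2. None of 11 primitive blood genes passed, while 6 were lower adjusted over the list alone, with a median of -1.43 (adjusted p = 3.18e-05, and adjusted p = 0.149 with an estimated correlation). The cathepsin gene Ctsh rose from 7.10 ± 1.59 to 125 ± 85.0 CPM. The secreted proteoglycan gene Nepn rose from 2.78 ± 2.34 to 206 ± 21.4 CPM, and Cdx2 from 0.809 ± 0.175 to 15.9 ± 0.337 CPM. In all 968 genes passed, 592 higher and 376 lower in the anterior-midgut section. The count was 201 without anterior replicate 1, 503 without anterior replicate 2, 212 without anterior-midgut replicate 1 and 1729 with DESeq2. Of 81 named genes past the threshold, 26 stayed past it with each library left out in turn, and the genes given here are among them.

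From the anterior-midgut to the midgut-posterior section, heart muscle genes fell and posterior patterning genes rose. Which cells of the sections carried the heart muscle transcripts was not tested. Ttn, which encodes titin, went from 49.3 ± 8.42 to 0.209 ± 0.00126 CPM, a log2 change of -7.87 (SE 0.80, adjusted p = 0.00525), and the atrial myosin gene Myl4 from 230 ± 39.3 to 1.68 ± 0.276 CPM. Of 16 cardiac and splanchnic genes, 4 fell (8 lower and 1 higher adjusted over the list alone; adjusted p = 2.11e-10, and 0.106 as the adjusted p with an estimated correlation). Of 12 midgut and hindgut genes, 4 rose (6 adjusted over the list alone), with Cdx2 going from 15.9 ± 0.337 to 70.0 ± 14.2 CPM. Of 11 Hox genes in groups 5 to 8, 4 rose, and of 14 in groups 9 to 13, 5 rose, led by Hoxb9 (0.597 ± 0.753 to 55.0 ± 4.61 CPM); adjusted over the list alone, 9 and 11 rose. Hepatopancreatic genes fell in 2 of 12 cases (5 adjusted over the list alone), Prox1 from 26.9 ± 5.59 to 6.39 ± 2.18 CPM and Onecut2 from 8.33 ± 0.534 to 1.83 ± 0.736 CPM. With an estimated correlation, the adjusted p was 0.0032 for hepatopancreatic and for midgut and hindgut genes and 0.00664 for both Hox lists.

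In that step none of 23 visceral endoderm genes passed in edgeR (0 adjusted over the list alone), and the median log2 change of the list was -0.04 while camera placed it upwards (adjusted p = 0.673). Without anterior-midgut replicate 2 the median was -0.59 (adjusted p = 0.0132), and without anterior-midgut replicate 1 it was 0.90 (adjusted p = 0.000213). In all 86 genes passed, 30 higher and 56 lower in the midgut-posterior section. Each library left out lowered this count, as 7 and 6 genes passed without anterior-midgut replicate 1 and 2, and 9 and 17 without midgut-posterior replicate 1 and 2. Hoxb9 and Hoxa7 alone, of 28 named genes past the threshold, stayed past it in each of these fits. The count was 251 with only these groups in the fit, 152 with no filter on low counts, 53 with the replicate number as a block and 443 with DESeq2. It was 140 with Y-linked gene levels as a covariate, a fit chosen after the data were seen.

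The posterior section rose above the midgut-posterior one in FGF, Wnt, neural tube, and epiblast and nascent mesoderm genes. Of 13 FGF genes, 6 rose (11 adjusted over the list alone), with Fgf8 going from 3.50 ± 2.56 to 79.1 ± 47.3 CPM and Fgf17 from 1.85 ± 0.834 to 50.3 ± 24.4 CPM. Of 16 Wnt genes, 8 rose and 1 fell (13 and 2 adjusted over the list alone), with Wnt5b going from 17.9 ± 0.236 to 135 ± 70.1 CPM. Of 16 epiblast and nascent mesoderm genes, 5 rose (8 adjusted over the list alone), with T going from 50.4 ± 1.54 to 339 ± 162 CPM. Of 12 neural tube genes, 3 rose (8 adjusted over the list alone; adjusted p = 3.92e-07). Hox genes of groups 9 to 13 rose in 9 of 14 cases and midgut and hindgut genes in 6 of 12 (12 and 9 adjusted over the list alone), Cdx2 by a log2 change of 1.92 (SE 0.22, adjusted p = 0.0021). All of these lists passed with an estimated correlation, with adjusted p-values of 0.0141 for FGF genes, 0.0388 for Wnt genes, 0.0365 for epiblast and nascent mesoderm genes, 0.0258 for neural tube genes, 0.0141 for the Hox genes and 0.0107 for midgut and hindgut genes. Of 11 parietal endoderm genes, 3 fell, and of 12 p53 response genes, 3 rose (7 and 5 adjusted over the list alone; adjusted p = 0.0353 and 0.0365 with an estimated correlation).

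Retinoic acid genes went the other way in this step, with Rarb going from 52.1 ± 2.84 to 13.4 ± 4.56 CPM and Aldh1a2 from 96.0 ± 3.87 to 13.3 ± 6.53 CPM. Of 11 measured, 4 fell and 1 rose (5 and 3 adjusted over the list alone), with an adjusted p = 0.0358, an adjusted p = 0.164 with an estimated correlation, 0.0833 without posterior replicate 1, 0.137 without posterior replicate 2 and 0.053 with no filter on low counts. The visceral endoderm list had 1 of 23 genes that fell, Mttp (14 adjusted over the list alone), and a median log2 change of -2.53 (adjusted p = 9.83e-17, and 0.164 as the adjusted p with an estimated correlation). In all 392 genes passed, 195 higher and 197 lower in the posterior section. The count was 65 without midgut-posterior replicate 1, 98 without midgut-posterior replicate 2, 65 without posterior replicate 1, 797 without posterior replicate 2, 17 with only these groups in the fit and 1299 with DESeq2. Of 51 named genes past the threshold, Cdx2, Cyp26a1, Dkk1, Rarb and Wnt5b stayed past it with each library left out in turn, and 0 did so in every setting.

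Dissociated cells carried more immediate early transcripts than bulk gut tubes. The list of 23 such genes, which respond within minutes to stimulation, had a median log2 difference of 1.84, with 18 higher when adjusted over the list alone and 0 over all genes tested. Fos stood at 276 and 388 CPM in the dissociated libraries and at 2.66 and 55.9 CPM in the bulk libraries, and Jun at 385 and 424 CPM against 52.7 and 83.8 CPM. Camera gave an adjusted p = 2.06e-36, the adjusted p was 0.121 with an estimated correlation, and fry gave an adjusted p = 0.0245. The list passed with each library left out in turn, the 1 list of 11 past the threshold here for which this held. Visceral endoderm genes had a median difference of 1.56, or 1.45 with genes at 0 counts set to their bound (adjusted p = 5.02e-06, adjusted p = 0.837 with an estimated correlation, and 0.128 without dissociated replicate 2). Primitive blood genes had a median difference of -1.22, with 6 of 11 lower when adjusted over the list alone (adjusted p = 6.1e-05, adjusted p = 0.453 with an estimated correlation, and 0.132 without dissociated replicate 1). Mitochondrially encoded genes had a median difference of -0.49 (0 of 10 passed, 0 adjusted over the list alone), with an adjusted p = 0.000635, an adjusted p = 0.808 with an estimated correlation, 0.114 without dissociated replicate 2 and 0.156 without bulk replicate 2. Heat shock genes had a median difference of 0.25 (0 of 13 passed, 3 higher adjusted over the list alone), with an adjusted p = 0.00566, an adjusted p = 0.756 with an estimated correlation, 0.337 without dissociated replicate 1 and 0.156 without bulk replicate 2. Fry gave adjusted p-values of 0.567 for visceral endoderm, 0.146 for primitive blood, 0.299 for mitochondrially encoded and 0.157 for heat shock genes. Cdx2 stood at 96.2 ± 11.2 CPM in dissociated cells and 89.8 ± 11.8 CPM in bulk tissue (adjusted p = 0.85).

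The dissociated libraries differed from each other more than the libraries of any other group, with an SD of log2 differences of 0.99 across 13737 genes against at most 0.84 elsewhere. Cardiac Actc1 stood at 65.8 and 666 CPM in dissociated replicates 1 and 2, and Apoa1 at 69.6 and 607 CPM. Sex-linked genes differed between them too, with Xist at 7.27 and 174 CPM and Uty at 22.5 and 1.88 CPM. In bulk replicates 1 and 2, Xist stood at 1.43 and 524 CPM and Uty at 22.3 and 11.6 CPM. How far this affects the calls was not tested. No gene passed over all genes tested in edgeR, where 2809 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0596. With the replicate number as a block 7 genes passed, and DESeq2 called 304 genes. Without dissociated replicate 1 the edgeR count was 4754, without bulk replicate 2 it was 5, and with the other libraries left out it was 0; 7 genes passed with no filter on low counts.

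**Figure D4:**
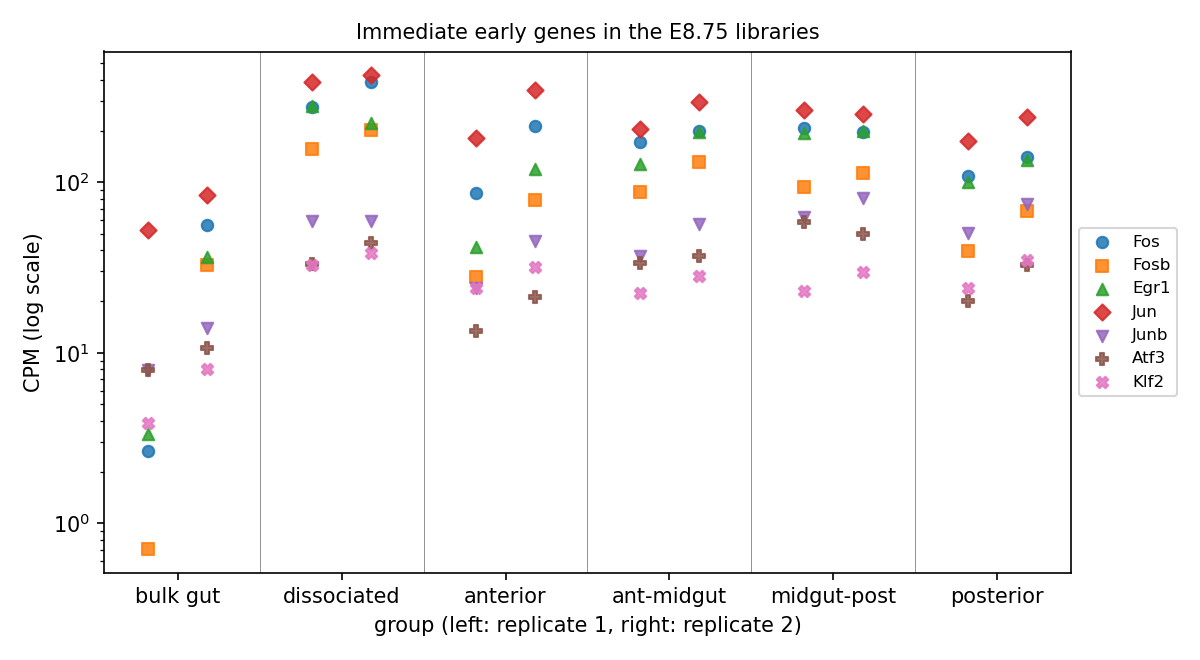
CPM on a log axis of 7 immediate early genes in the 12 gut tube libraries, with replicate 1 on the left and replicate 2 on the right of each group. Fos lay at 2.66 and 55.9 CPM in bulk gut tubes, at 276 and 388 CPM in dissociated cells and between 86.9 and 213 CPM in the sections.

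Bulk gut tubes at E8.75 were lower than emVE at E7.5 in visceral endoderm, lysosome, epiblast and mitochondrially encoded genes and higher in Hox, blood, vessel and heart genes. Of 23 visceral endoderm genes, 22 fell (23 adjusted over the list alone), with a median log2 change of -4.26 (adjusted p = 7.16e-11, and 0.332 as the adjusted p with an estimated correlation). Mttp went from 558 ± 20.2 CPM in emVE to 38.5 ± 12.5 CPM in bulk gut tubes, and Lrp2 from 384 ± 31.0 to 70.7 ± 6.70 CPM. Afp did not pass (759 ± 130 against 164 ± 76.1 CPM, adjusted p = 0.0778). Of 16 lysosome genes, 13 fell (13 adjusted over the list alone), Lamp1 from 693 ± 58.2 to 272 ± 14.2 CPM (list adjusted p = 1.84e-11, and 0.143 as the adjusted p with an estimated correlation). Of 16 epiblast and nascent mesoderm genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 3.76e-05, and adjusted p = 0.143 with an estimated correlation). Of 10 mitochondrially encoded genes, 7 fell (7 lower and 1 higher adjusted over the list alone), with a median of -1.30 (adjusted p = 0.000128, and adjusted p = 0.382 with an estimated correlation). In every library mt-Co1, mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd6 stood at 639 CPM or more. The other measured members stood at no more than 1.39 CPM in any library. The median and tests of this list include those low members in each comparison. Mitochondrial transcripts took 1.63% and 2.56% of the counts in the bulk libraries and 5.48% and 4.77% in the emVE libraries. Anterior visceral endoderm genes fell in 7 of 12 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 2.21e-06, and adjusted p = 0.0872 with an estimated correlation). Cer1 went from 284 ± 46.2 to 0.108 ± 0.152 CPM, the neuropeptide gene Trh from 773 ± 60.1 to 4.84 ± 1.71 CPM and Eomes from 37.2 ± 0.665 to 0.385 ± 0.0649 CPM.

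All 12 endothelial genes rose (12 adjusted over the list alone; adjusted p = 1.16e-13, and 0.138 as the adjusted p with an estimated correlation), and Emcn, at 0 counts in emVE, was at least 1126-fold higher. Of 11 primitive blood genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 5.24e-10, and adjusted p = 0.0872 with an estimated correlation); the embryonic globin Hba-x was at least 8535-fold higher. Hox genes rose in 11 of 12 cases in groups 1 to 4, 11 of 11 in groups 5 to 8 and 10 of 14 in groups 9 to 13 (the same counts adjusted over the list alone). Their adjusted p-values were 3.08e-11, 1.3e-14 and 5.36e-06, and 0.1, 0.0872 and 0.198 as adjusted p-values with an estimated correlation. Of 16 cardiac and splanchnic genes, 12 rose, and of 17 foregut genes, 11 rose (14 and 13 adjusted over the list alone; adjusted p = 0.266 and 0.445 with an estimated correlation). The pancreatic hormone genes Ins1 and Gcg, at 0 counts in emVE, stood at 36.0 ± 0.627 and 34.2 ± 0.00456 CPM in bulk gut tubes and were at least 1487-fold and 1416-fold higher. In all 6688 genes passed, 3763 higher and 2925 lower in bulk gut tubes, and 4242 passed without bulk replicate 1. Stage and tissue differed together in this comparison, so that it does not separate them.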

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

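The fit with Y-linked gene levels was chosen after the data were seen; all other alternatives were planned. For exVE against emVE, the count of genes past the threshold stayed within 1.5 times of 7605 in every alternative run. DESeq2 called more genes between sections: 2280 for the posterior against the anterior, 1729 for the anterior-midgut against the anterior, 443 for the midgut-posterior against the anterior-midgut, 1299 for the posterior against the midgut-posterior, 3739 for any difference, and 304 for dissociated against bulk tissue. With only the compared groups in the fit, which leaves 2 residual degrees of freedom, the midgut-posterior against the anterior-midgut section gave 251 genes and the posterior against the midgut-posterior section 17. With no filter, the former gave 152 genes and dissociated against bulk tissue gave 7. With the Y-linked gene level as a covariate the midgut-posterior against anterior-midgut count was 140. The cause was not tested for these.

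With the replicate number as a block, the midgut-posterior against the anterior-midgut section gave 53 genes and dissociated against bulk tissue gave 7; the cause was not tested. The block gave 1199 genes for the posterior against the anterior section, 832 for the anterior-midgut against the anterior, 304 for the posterior against the midgut-posterior, 7334 for exVE against emVE, 6390 for bulk gut tubes against emVE and 1980 for any difference among sections.

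Leaving out 1 library gave 5406 to 6285 genes for exVE against emVE, 615 to 1037 for the posterior against the anterior section, 201 to 694 for the anterior-midgut against the anterior, 6 to 17 for the midgut-posterior against the anterior-midgut, 65 to 797 for the posterior against the midgut-posterior, 0 to 4754 for dissociated against bulk tissue, 4242 to 4998 for bulk gut tubes against emVE and 1244 to 2246 for any difference among sections. A fit without a library has fewer samples, and a group left with 1 library adds no spread of its own.

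Of 231 list results, 115 passed with the preset correlation, 94 of these did not with an estimated one, and 21 passed in every setting. Of 553 named gene results past the threshold, 316 stayed past it in every setting. The list results whose camera direction changed did so with 1 library left out, with the cause not tested. Without dissociated replicate 1, foregut genes had a median difference between dissociated and bulk tissue of 0.28 (range -2.17 to 0.28). Without dissociated replicate 2, Hox groups 5 to 8 had a median of 0.37 there (range -0.70 to 0.37). Without anterior-midgut replicate 2, the midgut-posterior against anterior-midgut medians were -0.59 for visceral endoderm (range -0.59 to 0.90) and -0.27 for lysosome genes (range -0.27 to 0.35). Without posterior replicate 1, general endoderm and epithelium genes had a median of -0.33 between the posterior and midgut-posterior sections (range -0.33 to 0.59). With 57061536 to 84509973 counts per library and a chi-square per gene of at least 34.3 between libraries of a group, spread between libraries limits these calls more than depth, except for genes near 0 counts.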

Other observations

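All tests of this part were chosen after the results were seen, except for the tests of a low level in bulk gut tube replicate 1 and of the genes higher in exVE, where the fit of 4 libraries was added later.

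The middle sections of the gut tube held visceral endoderm transcripts at unequal shares of their level in exVE. Relative to exVE, the mean of the anterior-midgut and midgut-posterior sections was 104% for Afp, 29.0% for Ttr, 26.3% for the retinol carrier Rbp4 and 15.5% for Apoa1. It was 7.59% for Apob, 4.69% for the endocytic adaptor Dab2, 4.11% for the receptor Cubn and 0.555% for Apoc2. The median of the 23 list members was 10.2%. These shares compare means without a test. They also depend on the TMM factors, which were lowest in exVE (0.787 and 0.775). On library totals alone each share would be higher.

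Immediate early genes were higher in the sections than in bulk gut tubes. The sample titles mention dissociation only for whole gut tubes and do not say how the sections were handled. In a contrast of the mean log2 level of the 4 sections with bulk gut tubes, 10 of 23 rose in the sections (20 adjusted over the list alone), among them Jun (log2 1.84, adjusted p = 0.0102), Junb (log2 2.24, adjusted p = 0.00493) and Klf2 (log2 2.19, adjusted p = 0.00437). The list had an adjusted p = 9.29e-27, and an adjusted p = 0.0762 with an estimated correlation. A mean of log2 levels pulls down genes found in only some sections, so the count of all genes past the threshold, 327, is no measure of a difference in tissue. Hox genes of groups 9 to 13 had a median of -2.98 there with 8 past the threshold, and foregut genes -1.77 with 6, but with arithmetic mean CPM these medians were 0.59 and -0.22. The immediate early median was 1.62 with arithmetic means (21 of 23 above 0). The visceral endoderm median was 0.53 in the contrast (adjusted p = 0.0562) and 1.54 with arithmetic means (23 of 23 above 0), so a tissue list lay higher in the sections as well. Between dissociated cells and the sections the list median was 0.39, or 0.37 with arithmetic means, with 1 gene past the threshold (list adjusted p = 0.0327, and adjusted p = 0.74 with an estimated correlation).

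The higher immediate early genes in dissociated cells may reflect handling. Dissociation into single cells as the only cause is argued against by the sections, provided that these were not dissociated. Their sample titles do not mention dissociation, and they lay above bulk gut tubes by a list median of 1.59 on the log2 scale. That contrast was not run without bulk replicate 1, on which its size leans. The list medians were 2.995 and 4.402 log2 CPM in bulk replicates 1 and 2, and 4.578 to 5.634 over the section libraries. The list median of the lowest section library, posterior replicate 1, was thus only a little above that of bulk replicate 2. A gap between list medians is not a median of differences per gene. Each immediate early gene plotted by library was higher in posterior replicate 1 than in bulk replicate 2. Fosb stood at 39.7 against 32.9 CPM, Jun at 174 against 83.8 CPM and Junb at 50.7 against 13.9 CPM. The plotted genes were chosen after the values were seen. A low level in bulk replicate 1 alone is also argued against, because without that library the median between dissociated and bulk tissue was 1.71. With all libraries, camera with an estimated correlation gave the list an adjusted p = 0.12 in that comparison. A handling step or time shared by the dissociated and sectioned tissue stays open, since the labels give no times of handling, and a biological difference, such as in cell content, was not tested.

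Xist and Y-linked genes had differences of opposite sign between the anterior and posterior sections, none past the threshold. Xist stood at 368 and 432 CPM in the anterior libraries and 104 and 76.3 CPM in the posterior ones, while 4 Y-linked genes were higher posteriorly by a median log2 of 1.10 (SD 0.287). In 4 of 4 Y-linked genes both posterior libraries lay above both anterior ones, but none passed (adjusted p = 0.227 to 0.603). Different shares of male and female embryos and lower Xist per cell cannot be told apart with 2 libraries per section. For Xist the adjusted p was 0.54, where the spread was pooled over all groups and Xist stood at 1.43 and 524 CPM in bulk gut tubes. That pooled spread entered for the Y-linked genes as well, and Uty stood at 22.5 and 1.88 CPM in the dissociated libraries.

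Mesoderm and notochord genes were higher in emVE than in exVE, and 4 of 23 visceral endoderm genes were lower (list adjusted p = 0.00789, and adjusted p = 0.686 with an estimated correlation), for which a mixture of cell types in emVE is a candidate explanation. Dilution by cells without visceral endoderm transcripts as the only cause is argued against for that list, since in a fit of these 4 libraries the members ran from 0.13 for Spink1 (SE 0.079) to 2.27 for Lrp2 (SE 0.0928), with an SD 5.05 times their median SE. That ratio was 0.716 in the fit of all 16 libraries, where the median SE was 0.745 against 0.106, because the spread of gut tube libraries enters there. Of all genes higher in exVE, 4.08% exceeded the list median by more than 2 SE in the fit of 4 libraries and 1.47% in the fit of all 16, but the 2.5% set beforehand was a normal tail, and with 7.46 total degrees of freedom 4.16% lies past 2 SE, so this share decides nothing. Of 16 epiblast and nascent mesoderm genes, 13 were higher in emVE, but carried-over cells and expression by the embryonic visceral endoderm itself cannot be told apart, because no library of those cells was analysed and Dnmt3b was abundant in exVE too (563 against 461 CPM in emVE).

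Mitochondrial transcripts were seen in part only, with mt-Co1 between 1760 and 20500 CPM and mt-Co2 at no more than 1.05 CPM in any library. Dissociated replicate 2 had 0.959% of its counts in mitochondrial genes, the lowest share of the 16 libraries, and its Hoxb9 level was 21.99 CPM against 78.1 CPM in replicate 1.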
